A study of Manihot esculenta with 8 samples.

How the data were processed

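Friable embryogenic callus of the cassava varieties KU50 and 60444 was measured on 8 one-colour arrays, 4 per variety. Total RNA was labelled with Cy3 and hybridised to 1 slide holding all 8 arrays, which were read in 1 scan. The series describes the replicates as independent biological samples. Each array held 62976 spots, of which 1319 were control spots. The other 61657 spots carried 59079 probes of 60 bases, and 2578 probes had 2 spots. Each probe stood for 1 transcript name, so a count of genes apart from probes is not given. Several probes can carry 1 description, and a value belongs to the probe measured.

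The deposited spot intensity values came from Feature Extraction 10.7.3.1 per the file headers, as a background-subtracted and detrended processed signal, beside the raw spot mean and the local background. Per the file headers, the other columns used were flags per spot with the value 0 or 1 for well above background, positive and significant, outlier and saturated. The deposited value table held log2 values made by the authors, and the tool used for it is not given in the sources used here. Its columns had medians of -3.06, -3.11, -3.10 and -3.03 for KU50 replicates 1 to 4, and of -3.22, -3.23, -3.21 and -3.25 for 60444 replicates 1 to 4. Each column differed from the log2 processed signal of its own array by 1 constant, which set the array's 75th percentile to about 0. The scale and the centring were therefore read from the values, no column was a ratio, and neither scale, centring nor direction stayed unknown.

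Between 64.3% and 66.6% of the spots per array were well above background, 0 spots were saturated, and 14 spots over all arrays were left out as outliers. The median signal per array lay between 75.3 and 101 intensity units. Across the 1672 tested probes with 2 spots, the median absolute difference between the 2 spots was 0.09 on the log2 scale. The median SD between the 4 arrays was 0.14 for KU50 and 0.16 for 60444. The number of arrays limits the precision.

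The log2 processed signal was scaled to the 75th percentile of each array's probes, and spots of 1 probe were averaged. Probes well above background on all 4 arrays of at least 1 variety were tested, which left 38615 probes. The varieties were compared with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Tables were read with data.table version 1.17.8 and Python 3.11.15, and plots were drawn with matplotlib 3.10.9. A value written with ± is a log2 difference, KU50 minus 60444, with its standard error from limma and n = 4 arrays per variety. A probe well above background on all 4 arrays of 1 variety and on none of the other was given only a lower bound. The bound set the bright variety's mean against, on each dim array, the higher of the lowest well-above-background signal and the probe's own signal.

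Gene lists were drawn from words in the probe descriptions, which named a function for 38327 probes (64.9%). Of 38 lists, 37 had at least 5 tested probes and were tested with limma's camera at a preset inter-gene correlation of 0.01. The test was repeated with an estimated correlation, and fry was run as a description. The comparison, the lists, the thresholds, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were the 8 highest and 8 lowest differences among probes measured on all 8 arrays with separate groups and a described function, every member of the list of embryogenic regulators, up to 4 members of each other list by smallest adjusted p, and the 3 largest bounds each way. Some probes entered a list only through shared wording, such as lipid-transfer proteins whose description contains the words seed storage. Lists without such members, lists with 1 probe per description, 3 added lists, a camera test of every description carried by at least 10 tested probes, scaling to spike-ins and a Fisher's exact test of the lists for probes of 1 variety were chosen after seeing the data or the descriptions.

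The alternatives were quantile normalization, normexp background correction with an offset of 50, 2 other scalings, 2 other filters on dim probes, a replicate block, array weights, a trended robust fit, the authors' value table, and each array left out in turn. The transcript names matched 0 entries of the reference table used here, so no coordinates are given. The pipeline was tested on simulated data with the same arrays per variety, 38604 probes, 200 simulated changes and noise drawn independently for each probe. It recovered 100% of the changes of log2 size 2, 89.6% of those of size 1 and 25.4% of those of size 0.5, with 10 false calls among 153. With no simulated change, limma called 0 probes. Far fewer probes changed in the simulation than in the data, which makes the adjusted threshold stricter there, and its noise was not correlated between probes. The shares recovered and the false calls therefore do not carry over to this comparison.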

Results

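Friable embryogenic callus, a loose tissue of small embryogenic cell clusters that serves as the target for gene transfer in cassava, was profiled in the varieties KU50 and 60444. RNA from 4 independent samples of each variety was hybridised to arrays carrying 59079 probes, of which 38615 (65.4%) were tested. Across probes, which are not independent replicates, Pearson's r was 0.990 to 0.995 between KU50 arrays, 0.979 to 0.995 between 60444 arrays and 0.904 to 0.927 between varieties. Replicate 2 of 60444 stood apart, with r of 0.979 to 0.987 to the other 60444 arrays, which had r of 0.993 to 0.995 among themselves. Callus of KU50 had spent 5 months and callus of 60444 had spent 3 months on the medium that the labels abbreviate as FIM. Of this time, 3 months passed for KU50 and 1 month for 60444 until friable callus was seen, and a further 2 months passed for both. Each variety filled 1 row of the slide. Variety and culture time cannot be told apart in the comparison. Spike-in probes, scaled as the other probes, differed between the slide rows by a median of 0.09 on the log2 scale, in a test chosen after the values were seen.

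**Figure D1:**
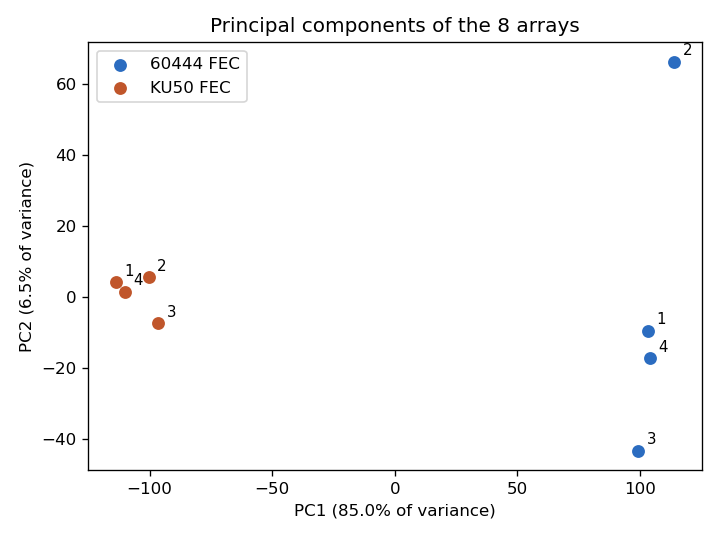
Principal components of the log2 signal of the 8 arrays, each point 1 array with its replicate number, coloured by variety. The horizontal axis carries 85.0% of the variance and separates the varieties, and the vertical axis carries 6.49% and sets 60444 replicate 2 apart.

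The comparison asked how KU50 callus, for which a transformation method was being set up, differs in gene expression from callus of 60444. Of LEA proteins and dehydrins, 40 probes were higher and 10 lower in KU50, with a seed maturation protein (JGIv7_cassava4.1_033303m) at 6.04 ± 0.41 (limma adjusted p = 6.34e-06, n = 4 per variety). The seed storage list was split, but without lipid-transfer proteins that share its wording 12 of 15 probes were higher and 1 lower. That form of the list was chosen after seeing the data. Of pathogenesis-related proteins, 44 probes were higher and 15 lower, led among measured probes by a homolog of the carrot EP3-3 chitinase (JGIv7_cassava4.1_014554m) at 7.18 ± 0.27 (limma adjusted p = 2.38e-07). The camera calls of the LEA and pathogenesis-related lists did not hold with an estimated correlation or with 1 probe per description. Gibberellin 20 oxidase 2, an enzyme of gibberellin synthesis, was lower in KU50 on 3 of 4 probes, at -4.95 ± 0.24 on JGIv7_cassava4.1_020947m (limma adjusted p = 9.14e-07). Both probes for the homeobox gene WUSCHEL related homeobox 5 were lower in KU50.

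The difference was broad. Of the tested probes, 24345 (63.0%) changed, 12264 higher and 12081 lower in KU50. The balance turned with the scaling, to 10998 higher and 13455 lower with quantile normalization and 9403 and 10604 with spike-ins, the latter chosen after seeing the data. At least 2-fold changes numbered 7345, with 4473 higher and 2872 lower, and normexp background correction brought this count to 3829. The share of these that was higher was 60.9%, and 54.4% to 64.3% over the 6 other scalings. The 4 arrays of 1 variety lay above all 4 of the other for 59.3% of the tested probes, where chance gives 2.86%. With limma's camera, 10 of 37 gene lists shifted, 8 higher and 2 lower in KU50. None of these calls held with an estimated correlation, where 0 lists passed, 1 had an unadjusted p under 0.05, and fry called 21. With 1 probe per description, an alternative chosen after seeing the data, camera called 0 of 35 lists, 7 had an unadjusted p under 0.05, and fry called 23. Without a filter on dim probes only the list of LEA proteins and dehydrins kept its call, and with array weights 3 lists did, the others being starch and sucrose metabolism and pathogenesis-related proteins. Over the 6 other scalings 0 of the 10 medians changed sign, and 8 shrank by over 1.5 times with normexp. These reached 0.56 for LEA proteins, 0.33 for pathogenesis-related proteins, 0.16 for NLR genes, 0.21 for starch and sucrose, 0.16 for senescence, 0.19 for hypoxia, -0.16 for auxin response and -0.20 for photosynthesis.

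**Figure D2:**
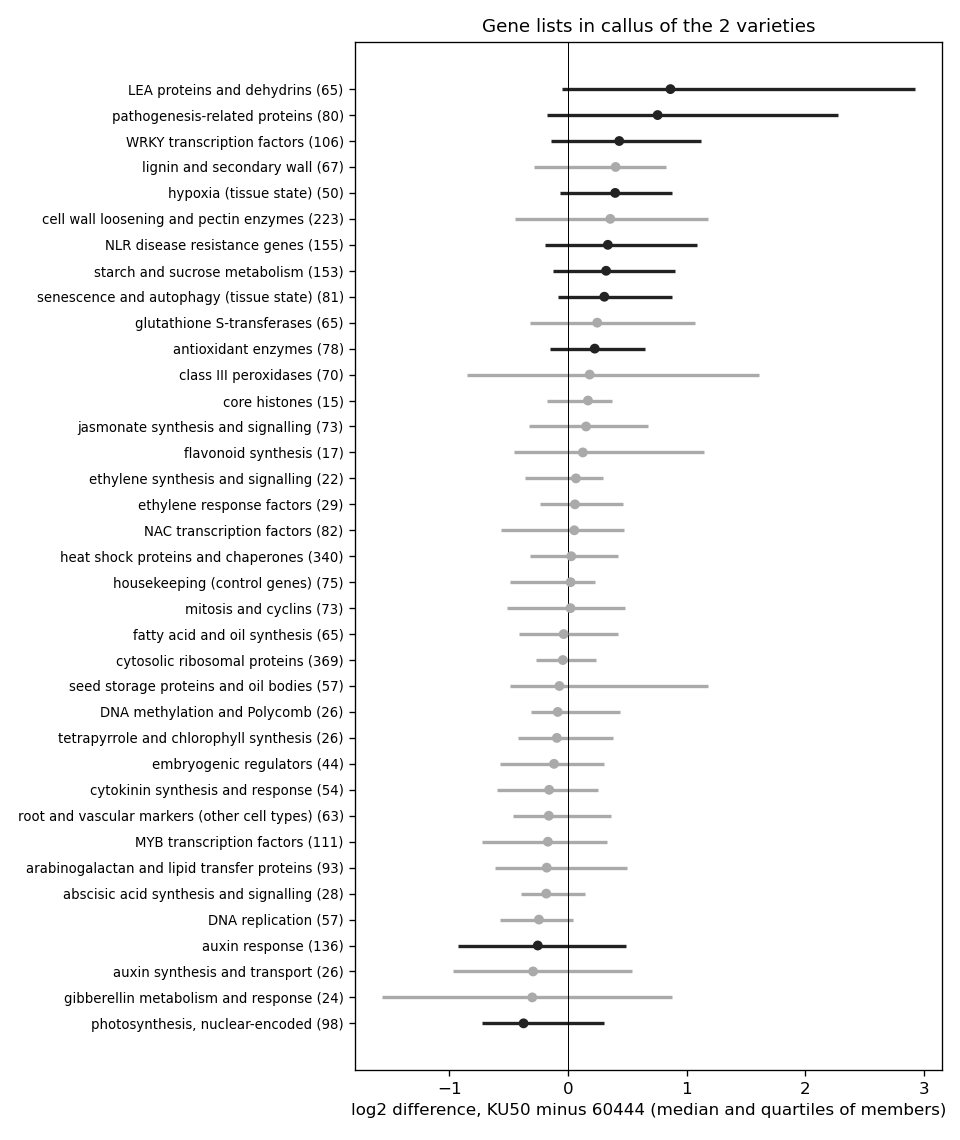
Median (point) and quartiles (line) of the log2 difference, KU50 minus 60444, over the tested members of each of the 37 gene lists, with the number of members in brackets. Black marks the 10 lists called by camera at the preset correlation and grey the others, and LEA proteins and dehydrins have the highest median at 0.86.

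LEA proteins and dehydrins, which accumulate as seeds dry, were higher in KU50 for 40 and lower for 10 of 65 probes, with 15 not passing. Adjusted over the list alone, 40 were higher and 12 lower. The median was 0.86 (camera adjusted p = 0.00343, and adjusted p = 0.810 with an estimated correlation). A seed maturation protein (JGIv7_cassava4.1_025519m) was higher at 4.16 ± 0.21. Of the hydroxyproline-rich glycoproteins that share the LEA wording, EST_Contig10933 was higher at 2.23 ± 0.09, 454_F7JABCT01AJYJ4 was lower at -1.92 ± 0.09, and JGIv7_cassava4.1_029611m was at least 2.58-fold higher (limma adjusted p = 1.31e-06). Without such members 24 of 28 probes were higher and 1 lower, with a median of 2.35 (camera adjusted p = 9.18e-06, and adjusted p = 0.797 with an estimated correlation).

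Seed storage proteins and oil bodies went both ways, with 22 higher, 18 lower and 17 not passing of 57 probes, and 24 higher and 18 lower adjusted over the list alone. Their median of -0.07 differed in sign from their mean of 0.55 and from the test, which pointed up without passing (camera adjusted p = 0.633). The members with the smallest adjusted p were lipid-transfer proteins that share the wording, among them 454_Contig09633 at -4.06 ± 0.16 and JGIv7_cassava4.1_025645m at 5.10 ± 0.23. Without members of this kind, 12 of 15 probes were higher and 1 was lower, with a median of 1.94 (camera adjusted p = 0.0102, and adjusted p = 0.797 with an estimated correlation), or 1.09 and 1.00 with normexp and 75th percentile or quantile scaling. Chosen after their values were seen, oleosin 1 was higher at 4.71 ± 0.56, seed storage albumin 5 (JGIv7_cassava4.1_028018m) at 3.99 ± 0.53 and 2 cupins at 5.33 ± 0.65 and 5.10 ± 0.66. The 60444 arrays varied for these transcripts. Relative to the array's 75th percentile, oleosin 1 was at 1.00 on 60444 replicate 3 (others -1.86 to -0.71). The cupin at 5.33 was at 0.43 there (others -2.59 to -2.16). Genes of fatty acid and oil synthesis did not pass as a list, with 15 higher and 22 lower of 65 probes, the same adjusted over the list alone. Their median of -0.04 and the test pointed down, the mean of 0.02 pointed up, and the median turned positive in 1 of 6 other scalings.

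**Figure D3:**
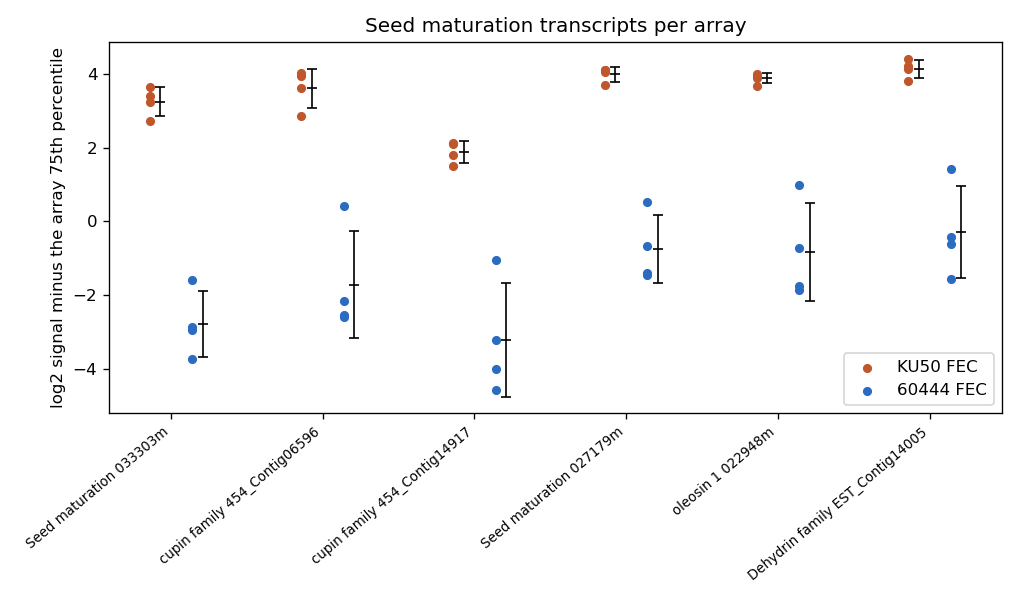
Log2 signal minus the array's 75th percentile for 6 maturation transcripts, the highest differences measured on all 8 arrays and chosen after their values were seen. Each coloured point is 1 array, the bar beside each group gives its mean and SD over 4 arrays, all KU50 arrays lie above all 60444 arrays, and 60444 replicate 3 is the highest of its group for each transcript.

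Embryogenic regulators, a list drawn up for transcription factors and receptor kinases tied to embryo identity, went both ways. It also held members matched only by wording, whose names do not show a tie to embryo identity. No tested member was described as LEC1, LEC2, FUS3, ABI3, BBM, WUS or AGL15 itself, so the list does not assess these regulators. Of 44 probes 13 were higher, 19 were lower and 12 did not pass, with the same counts adjusted over the list alone. The median was -0.12, and the list was not called (camera adjusted p = 0.405). Without the members set aside as matched only by wording, an alternative chosen after seeing the data, 6 were higher and 13 lower of 23, with a median of -0.40 that stayed negative in the 6 other scalings, and the list did not pass either (camera adjusted p = 0.165). These 23 still held ABI3-interacting protein 3, matched through the name ABI3, and its value of -0.40 was the median itself. Somatic embryogenesis receptor-like kinase 2 was higher at 3.94 ± 0.21 and 1.87 ± 0.10 on 2 probes and did not pass on another, at 0.15 ± 0.10. Normexp with quantile normalization brought the value of 1.87 to 1.24. Of 6 probes for somatic embryogenesis receptor-like kinase 1, 2 were higher at 1.93 ± 0.27 and 0.44 ± 0.15, 2 were lower at -1.62 ± 0.10 and -0.70 ± 0.11, and 2 did not pass. WUSCHEL related homeobox 5 was at least 5.84-fold lower in KU50 on EST_DV442336, above background on 0 of 4 KU50 arrays (limma adjusted p = 7.47e-06). Its other probe, above background on 3 of 4 KU50 arrays, was at -3.09 ± 0.27, and at -1.71 with normexp background correction.

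WUSCHEL related homeobox 11 was lower on both probes, at -1.35 ± 0.21 and -1.21 ± 0.13, and WUSCHEL related homeobox 1 was lower at -0.76 ± 0.19 and -0.37 ± 0.13. WUSCHEL related homeobox 13 was lower on 1 probe at -0.53 ± 0.07 and higher on another at 0.39 ± 0.08. WUSCHEL related homeobox 8 was higher by 0.19 ± 0.06, and WUSCHEL related homeobox 2 did not pass at 0.10 ± 0.15, though it did without 60444 replicate 2, at 0.25 (limma adjusted p = 0.0494). AINTEGUMENTA-like 5 was lower at -0.78 ± 0.07 and -0.97 ± 0.14, and AINTEGUMENTA-like 6 at -0.56 ± 0.08. ABI3-interacting protein 3 was lower at -0.40 ± 0.07. The members set aside as matched only by wording were split. Suppressor of abi3-5 was higher on probes at 1.05 ± 0.15 and 0.60 ± 0.13 and lower at -0.63 ± 0.08 and -0.51 ± 0.13, and WUS-interacting protein 2 ranged from 0.72 ± 0.18 to -0.52 ± 0.07. The probes at 0.60 and -0.51 are named EST_CAS01_005_P17.f and EST_CAS01_005_P17.r, so their opposite signs need not stand for separate genes. FUS3-complementing gene 1 was lower on 2 of 5 probes at -0.97 ± 0.11 and -0.30 ± 0.09, FUS3-complementing gene 2 was higher on 1 of 4 at 0.30 ± 0.11, and the genes related to ABI3/VP1 were higher at 0.36 ± 0.10 and 0.26 ± 0.09. Of the smaller changes, the calls for WUSCHEL related homeobox 8, somatic embryogenesis receptor-like kinase 1 at 0.44 and WUSCHEL related homeobox 1 at -0.37 were lost in 10, 9 and 8 of 20 alternatives. Those for FUS3-complementing gene 2, the gene related to ABI3/VP1 at 0.26 and WUS-interacting protein 2 at -0.19 were lost in 7 each. Leaving out 1 array ended these 6 calls for 5, 6, 7, 5, 5 and 4 of the 8 arrays in this order, with limma adjusted p up to 0.0704, 0.0809, 0.0989, 0.102, 0.0782 and 0.0678. WUSCHEL related homeobox 1 at -0.76 lost its call with normexp and 75th percentile scaling, at -0.21 (limma adjusted p = 0.0513). Scaling to spike-ins also ended the calls for WUSCHEL related homeobox 13 at 0.39, FUS3-complementing gene 1 at -0.30 and the gene related to ABI3/VP1 at 0.36.

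Among lists added after the descriptions were read, B3-domain factors were lower for 20 and higher for 3 of 30 probes, with a median of -0.56 (camera adjusted p = 4.2e-05, and adjusted p = 0.0722 with an estimated correlation). The largest difference of that list was upward, at 3.16 ± 0.70 on JGIv7_cassava4.1_028222m, and the lowest value was -2.66 ± 0.20. NF-Y subunits, whose family includes regulators of embryo development, were lower for 23 and higher for 3 of 40 probes, with a median of -0.31 (camera adjusted p = 0.000612, and adjusted p = 0.0722 with an estimated correlation). Subunit B6, which the wording of the embryogenic regulator list aimed at but missed, was lower at -0.25 ± 0.07 (limma adjusted p = 0.0139). Members of the histone superfamily were higher for 23 and lower for 5 of 41 probes (camera adjusted p = 0.0094, and adjusted p = 0.299 with an estimated correlation). These p-values were adjusted over the 3 added lists alone. In the test of 403 descriptions, the 41 histone superfamily probes did not pass (camera adjusted p = 0.0924). There, 28 AP2/B3-like probes passed (camera adjusted p = 0.00256, and adjusted p = 0.905 with an estimated correlation).

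Pathogenesis-related proteins were higher for 44, lower for 15 and not passing for 21 of 80 probes, and higher for 46 and lower for 15 adjusted over the list alone. Their median was 0.76, 0.72 with bounds in place of fitted values, 0.33 with normexp and quantile normalization and 0.16 without a filter on dim probes (camera adjusted p = 0.0249, and adjusted p = 0.810 with an estimated correlation). Osmotin 34 was at least 508-fold higher in KU50 (limma adjusted p = 4.44e-09), and a chitinase (454_GHRYMOR01BX336) was at least 191-fold higher (limma adjusted p = 2.24e-07), the only 1 of 5 probes with its description that was higher, with 2 lower. NLR disease resistance genes, which encode intracellular immune receptors, were higher for 75 and lower for 32 of 155 probes, and for 76 and 33 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.0413, and adjusted p = 0.810 with an estimated correlation). A TIR-NBS-LRR gene was at least 15.3-fold higher (limma adjusted p = 2.42e-08) and an NB-ARC gene (EST_Contig12248) was higher at 4.05 ± 0.15, while JGIv7_cassava4.1_000368m was lower at -1.77 ± 0.08. The NLR call was lost without 60444 replicate 2 (camera adjusted p = 0.0583). WRKY transcription factors were higher for 55 and lower for 20 of 106 probes, the same adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.0469, and adjusted p = 0.810 with an estimated correlation). Their members with the smallest adjusted p, WRKY DNA-binding proteins 70 and 7, were lower at -2.09 ± 0.08 and -2.35 ± 0.12, on 1 of 3 probes with 1 higher and on 5 of 6 probes, and the call was lost without 60444 replicate 2 (camera adjusted p = 0.0583) or KU50 replicate 3 (camera adjusted p = 0.0813).

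Starch and sucrose metabolism was higher for 80 and lower for 28 of 153 probes, and for 81 and 29 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.0187, and adjusted p = 0.810 with an estimated correlation). The word invertase also brought in plant invertase/pectin methylesterase inhibitors. Without members matched only by wording, chosen after seeing the data, 53 were higher and 23 lower of 109 probes. The median was then 0.25 (camera adjusted p = 0.0418, and adjusted p = 0.329 with an estimated correlation). An ADP-glucose pyrophosphorylase (454_Contig09498) was higher at 3.15 ± 0.09, with 3 of 5 probes of its description lower, and cytosolic invertase 2 was higher on 3 of 4 probes, at up to 3.18 ± 0.11. The value of 3.18 fell to 1.56 in the alternative that shrank it most. Isoamylase 1 was lower on 1 of 4 probes, at -2.96 ± 0.12. Antioxidant enzymes were higher for 40 and lower for 18 of 78 probes, the same adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.0469, and adjusted p = 0.810 with an estimated correlation). Manganese superoxide dismutase 1 was higher at 3.98 ± 0.12 and peroxiredoxin IIF at 1.44 ± 0.06. The antioxidant call was lost without KU50 replicates 2 or 3 or 60444 replicates 2 or 4 (camera adjusted p = 0.0649, 0.0813, 0.0663 and 0.0543).

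Senescence and autophagy genes were higher for 40 and lower for 12 of 81 probes, the same adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0413, and adjusted p = 0.810 with an estimated correlation). Senescence-related gene 3 was at least 20.7-fold higher and metacaspase 1 (EST_Contig14542) at least 10.1-fold higher (limma adjusted p = 1.62e-09 and 4.05e-07), the latter with 4 of 7 probes higher and 1 lower, and the call was lost without 60444 replicate 2 (camera adjusted p = 0.0583). Hypoxia genes were higher for 26 and lower for 9 of 50 probes, and for 26 and 11 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.0469, and adjusted p = 0.810 with an estimated correlation). A pyruvate decarboxylase (EST_Contig07778) was higher at 1.71 ± 0.08, and pyruvate decarboxylase-2 was split over 4 probes, with EST_Contig11642 at least 22.0-fold lower in KU50 (limma adjusted p = 8.32e-07), 1 at -0.53, 1 not passing and 1 higher at 0.87. Wound-responsive proteins, which the definition of the list named, were split, with 6 higher and 5 lower of 15 probes of that description. EST_CAS01_017_E13.f and 454_Contig03266 were among the lower at -2.97 ± 0.09 and -2.17 ± 0.08. A form of the list chosen after seeing the data left out these proteins and some other members. It had 19 higher and 2 lower of 32 probes (camera adjusted p = 0.00401, and adjusted p = 0.528 with an estimated correlation). The hypoxia call was lost without KU50 replicate 2 or 60444 replicate 2 (camera adjusted p = 0.0573 and 0.0583).

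Auxin response genes were lower for 65 and higher for 36 of 136 probes, the same adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0469, and adjusted p = 0.810 with an estimated correlation). A SAUR-like gene (JGIv7_cassava4.1_020173m) was lower at -4.53 ± 0.18 and indole-3-acetic acid inducible 9 at -1.59 ± 0.07. The 32 SAUR-like probes went both ways, with 11 higher and 16 lower and values from -4.53 to 5.45. The auxin call was lost in 11 of 20 alternatives, among them the replicate block, which joins arrays of 1 slide column (camera adjusted p = 0.0588). It was also lost without KU50 replicate 2 or 60444 replicates 1, 3 or 4 (camera adjusted p = 0.0649, 0.0637, 0.0641 and 0.0554). Nuclear photosynthesis genes were lower for 46 and higher for 20 of 98 probes, and for 47 and 21 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.0471, and adjusted p = 0.810 with an estimated correlation). Photosystem I light harvesting complex gene 1 was lower at -1.95 ± 0.07 and -2.08 ± 0.09. The photosynthesis call was lost without KU50 replicate 2 or 60444 replicates 2 or 3 (camera adjusted p = 0.0761, 0.0583 and 0.0708), and without a filter on dim probes the median was 0.00340 (camera adjusted p = 0.193).

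Other hormone lists did not pass, and with the growth and remaining lists their camera adjusted p ran from 0.114 to 0.934. Gibberellin genes were higher for 7 and lower for 11 of 24 probes, the same adjusted over the list alone (camera adjusted p = 0.697), and the other gibberellin 20 oxidase 2 probe among the 4 with the smallest adjusted p was lower at -4.80 ± 0.40, above background on 3 of 4 KU50 arrays. That probe was at -2.72 in the alternative that shrank it most. Chosen after their values were seen, the remaining probes for this enzyme were lower at -0.80 ± 0.27 and higher at 1.00 ± 0.12, and gibberellin 3-oxidase 1 was lower at -3.60 ± 0.54 and -1.62 ± 0.38. Gibberellin-regulated proteins were split, with EST_Contig06534 higher at 2.23 ± 0.17 and 454_Contig14173 at 1.77 ± 0.10, and 454_Contig07856, chosen after its value was seen, lower at -2.55 ± 0.25. Cytokinin genes were higher for 9 and lower for 24 of 54 probes, with response regulator 24 higher at 3.85 ± 0.12. Response regulator 11 was lower at -1.43, and histidine kinase 2 was lower at -1.60 and -1.91 on 2 of 4 probes. Auxin synthesis and transport had 8 higher and 11 lower of 26, abscisic acid 5 and 9 of 28, jasmonate 27 and 21 of 73, ethylene synthesis and signalling 5 and 8 of 22, and ethylene response factors 10 and 8 of 29. Adjusted over the list alone, the counts in these hormone lists were the same but for abscisic acid, with 5 and 8. ACC synthase 1, an enzyme of ethylene synthesis, was higher on 1 probe at 3.22 ± 0.18 and lower on the other two.

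Of the growth lists, DNA replication was lower for 23 and higher for 6 of 57 probes, the same adjusted over the list alone, with ribonucleotide reductase 1 lower on JGIv7_cassava4.1_021751m at -1.98 ± 0.14 and higher on its other probe at 0.38 ± 0.11. The list did not pass (camera adjusted p = 0.114), though it did without 60444 replicate 3 (camera adjusted p = 0.0221). Mitosis and cyclins had 26 higher and 26 lower of 73 probes, with cyclin D3;1 lower at -1.78 ± 0.10 and -1.84 ± 0.14, and a median of 0.02 against a mean of -0.06 and a test pointing down. That median turned negative in 3 of 6 other scalings. Ribosomal proteins had 75 higher and 91 lower of 369, core histones 7 and 3 of 15, and DNA methylation and Polycomb genes 8 and 8 of 26. Housekeeping genes had 16 higher and 28 lower of 75, with a median of 0.02 against a mean of -0.16 and a test pointing down, and their median turned negative in 3 of the 6 other scalings. Adjusted over the list alone, these counts were the same but for ribosomal proteins, with 71 and 73. Tubulin alpha-2 was lower on 1 of 2 probes, at -3.69 ± 0.13. Tubulin beta 8 was higher on 5, lower on 3 and not passing on 6 of 14 probes, with FGv7_scaffold08379_FGENESH3 at 2.48 ± 0.11, and at 1.14 in the alternative that shrank it most.

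The remaining lists did not pass either. Not passing does not show that a list was unchanged. The medians were 0.36 for cell wall enzymes and 0.40 for lignin genes, above the 0.34 of the called NLR genes. Over the 6 other scalings these medians fell as low as 0.20, 0.14 and 0.16. Cell wall loosening and pectin enzymes had 101 higher and 62 lower of 223 probes, with a pectin lyase-like gene (JGIv7_cassava4.1_021584m) at 4.91 ± 0.09, although 28 of the 58 probes of that description were lower and 16 higher. Lignin genes had 22 and 13 of 67, class III peroxidases 32 and 19 of 70, glutathione S-transferases 30 and 16 of 65, and flavonoid synthesis 7 and 5 of 17. Flavonol synthase 1 (EST_FF380068) was at least 27.7-fold higher in KU50 (limma adjusted p = 1.32e-08). MYB factors had 26 higher and 42 lower of 111, heat shock proteins 108 and 85 of 340, tetrapyrrole synthesis 7 and 7 of 26, and arabinogalactan and lipid transfer proteins 26 and 32 of 93. NAC factors had 23 higher and 23 lower of 82, with a median of 0.05 against a mean of -0.13 and a test pointing down, and the median turned negative in 1 of 6 other scalings. Root and vascular markers had 16 higher and 24 lower of 63, and moved apart, with phloem protein 2-B15 at least 79.9-fold higher and vascular related NAC-domain protein 1 at least 6.55-fold lower in KU50 on 1 of 2 probes (limma adjusted p = 1.97e-07 and 5.79e-07). Adjusted over the list alone, the counts of these remaining lists were the same but for cell wall enzymes with 102 and 63, lignin genes with 21 and 12, and heat shock proteins, with slightly fewer each way. The list of cyanogenic glucoside metabolism had 2 probes and was not tested, and both were acetone-cyanohydrin lyases, higher at 1.35 ± 0.09 and 1.31 ± 0.18. Their lowest values over 20 alternatives were 0.78 and 0.95.

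The highest measured differences also included a polyketide cyclase (EST_DV457011) at 6.82 ± 0.73, a ribosomal protein S4 (454_GHRYMOR02HXQ4V) at 6.73 ± 0.12, a stress induced protein at 6.27 ± 0.54, cytochrome P450 CYP81H1 at 6.21 ± 0.25, methyl esterase 5 at 5.86 ± 0.16 and a peroxidase (JGIv7_cassava4.1_024068m) at 5.79 ± 0.36. The lowest included an adenine nucleotide alpha hydrolase-like protein at -5.21 ± 0.16, an ankyrin repeat protein at -5.15 ± 0.28, a calcium-binding EF-hand protein at -4.81 ± 0.18, a GNS1/SUR4 membrane protein at -4.50 ± 0.18, a DNA/RNA polymerase superfamily protein at -4.31 ± 0.29 and 1 of 2 probes for beta-glucosidase 47 at -4.26 ± 0.35, the other being higher. The ribosomal protein S4 probe was the only 1 of 10 with its description that was higher, and 3 were lower. Among 403 descriptions tested after seeing the data, camera called 18, with cysteine-rich receptor-like kinase 8 higher for 18 and lower for 3 of 21 probes (camera adjusted p = 0.00159, and adjusted p = 0.905 with an estimated correlation).

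Detection in 1 variety alone was seen for 785 probes in KU50 and 440 in 60444. With the positive and significant call in place of the well-above-background call, the counts were 312 and 177. The largest bounds in KU50 were a dirigent-like protein at least 601-fold higher, osmotin 34, and cytochrome P450 CYP714A2, with 2 of 3 probes higher and 1 lower, at least 228-fold higher (limma adjusted p = 1.69e-07 and 2.56e-09 for the dirigent-like protein and CYP714A2). In 60444 the largest bounds were 2 UDP-glycosyltransferases, at least 212-fold and at least 141-fold lower in KU50, and a RAC-like 2 probe (454_Contig00917), at least 64.0-fold lower (limma adjusted p = 7.69e-11, 1.01e-09 and 3.79e-10). Of the 10 probes for RAC-like 2, 1 was lower, 2 were higher and 7 did not pass. Pathogenesis-related proteins were over-represented in a test chosen after seeing the data, with 8 probes in KU50 alone and 3 in 60444 alone, 13.8% of the list against 3.15% of other probes (2-sided Fisher's exact test, adjusted p = 0.00168 over the lists). That test takes probes as independent, although several can stand for 1 gene, so its p-value may be too small.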

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

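Of the tests in this part, the spike-in test was chosen after its values were seen. Each named probe's 4 arrays per variety, and 4 measures of overall signal per array, were searched for an array far from the other 3, by Dixon's critical value for groups of 4. This marked 26 of 412 groups (6.31%), where chance marks about 1 in 20 groups, and 7 of the 26 lay on 60444 replicate 2. Values are log2 signals relative to the array's 75th percentile.

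On 60444 replicate 2 the ribosomal protein S4 probe was at -4.35 (others -4.77 to -4.70), FUS3-complementing gene 1 at -0.81 (others -0.78), the gene related to ABI3/VP1 1 at -0.71 (others -0.50 to -0.48) and WUSCHEL related homeobox 8 at 4.64 (others 4.73 to 4.74). On the same array a lipid-transfer protein (454_Contig09633) was at 3.44 (others 3.90 to 3.99), ERF domain protein 12 at -2.35 (others -1.91 to -1.82) and a senescence/dehydration-associated protein at 0.22 (others -0.18 to -0.12). On 60444 replicate 1 AINTEGUMENTA-like 5 was at -0.53 (others -0.52), a lipid-transfer protein (454_GHRYMOR02I60OT) at 1.92 (others 1.67 to 1.71), an abscisic acid binding protein at 0.51 (others 0.67 to 0.68) and ADP-glucose pyrophosphorylase at -3.20 (others -2.96 to -2.94). On 60444 replicate 3 a peroxidase (JGIv7_cassava4.1_024068m) was at -1.12 (others -2.79 to -2.68).

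In KU50, replicate 1 had cyclin D3;1 (EST_CAS03_027_D14.f) at -1.34 (others -1.05 to -1.03), flavonol synthase 1 at -1.29 (others -0.68 to -0.63) and a wound-responsive protein at -4.06 (others -3.77 to -3.72). Replicate 2 had somatic embryogenesis receptor-like kinase 1 at -1.25 (others -1.38 to -1.37) and WUSCHEL related homeobox 5 at -6.11 (others -7.57 to -7.33), the latter below the well-above-background level. Replicate 3 had an NB-ARC gene at 1.47 (others 1.66 to 1.69), an invertase inhibitor at -0.50 (others -0.22 to -0.19), chromomethylase 3 at 1.30 (others 1.51 to 1.52) and a pyruvate decarboxylase at 4.60 (others 4.77 to 4.80). Replicate 4 had a LEA hydroxyproline-rich glycoprotein at -1.53 (others -1.81 to -1.77), cyclin D3;1 (JGIv7_cassava4.1_009900m) at -0.0173 (others -0.56 to -0.49), cyclin D3;2 at 1.48 (others 1.03), an auxin efflux carrier at -0.23 (others -0.42 to -0.39) and an acetone-cyanohydrin lyase at -2.04 (others -2.31 to -2.28).

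The broad difference between the varieties was weighed against chance, 1 unusual array and position on the slide. Of the 35 splits of the 8 arrays into 4 and 4, the real one gave 24345 changed probes, against 0 for the highest other split. All other splits mix the varieties, which puts their difference into the spread within groups. Low counts there thus follow from the separation of the arrays by variety, and the splits alone cannot exclude chance. With 35 splits, no share below 1 in 35 is possible. Without 60444 replicate 2 the count was 24937, which argues against that array as the source. Spike-in probes, which are added to every RNA, differed between the slide rows by a median of 0.0434 on the log2 scale over 8 probes after centring on their mean, which removes a shift common to all of them. Scaled to the 75th percentile as in the comparison and not centred, they differed by a median of 0.09 and at most 0.15. The changed probes, selected for their difference, had a median of 0.69. Over all tested probes, the median absolute difference between a KU50 and a 60444 array was 0.39 to 0.55. Both lie above the spike-in values, which argues against a slide effect of the spike-ins' size as the source. The spike-ins used were well above background on every array, so a slide effect limited to dim probes was not tested. The variety itself and the time on the medium stay open.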

How the results depend on the processing

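Of the settings in this part, scaling to spike-ins, 1 probe per description and lists without members matched only by wording were chosen after seeing the data. The number of changed probes ran from 20007 (spike-ins) to 26592 (array weights), within 1.5 times of 24345, and 0 named genes and 0 lists turned direction past the threshold. Quantile normalization shared 22925 changed probes with the reported result. At least 2-fold changes fell to 3829 with normexp and 75th percentile scaling and to 3792 with normexp and quantile normalization. The offset of 50 added there compresses differences of dim probes by construction, and 61 and 63 named values moved by over 1.5 times. The number of shifted lists, 10 as reported, was 1 without a filter on dim probes, 3 with array weights, 0 with an estimated correlation and 0 with 1 probe per description. Lists had far fewer members in the last of these, and for the others the cause was not tested. With the positive and significant call, 312 probes were detected in KU50 alone and 177 in 60444 alone, since dimmer spots then count as detected.

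With each array left out, changed probes ran from 21459 to 24937, 2-fold changes from 7046 to 7682, shifted lists from 4 (without 60444 replicate 2) to 10, probes in KU50 alone from 806 to 910 and the count in 60444 alone stayed within 1.5 times of 440. Without KU50 replicate 2, 6 lists shifted. List calls were lost 46 times and gained 1 time over 20 settings of scaling, filter, model and arrays, all with camera at the preset correlation, and only the LEA list kept its call in each of these. Of 190 named probes past the threshold 180 stayed past it in every setting. The 10 others, with differences between -0.76 and 0.44, were members of the list of embryogenic regulators, 5 of them matched only by wording, and each of the 8 arrays, when left out, ended at least 1 of these calls. That list was named in full, with 13 probes higher and 19 lower as reported. Most other named probes were picked for large differences or small adjusted p in these same data, so the count of 180 says little about other probes. Scaling to spike-ins shared 19773 of the 24345 changed probes.

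Same-number arrays of the varieties had residual correlations of 0.04, 0.12, 0.12 and 0.08, and a replicate block gave 23620 changed probes. Photosynthesis and auxin response lost their calls most often, in 9 and 11 of 20 settings. The mean of several probes per gene was not run, because each transcript name has 1 probe. Signal over background limits the probes of 1 variety to lower bounds.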

Other observations

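Of the tests in this part, those of probe mismatch for the maturation genes and of green tissue were chosen after the result was seen. With 1 probe per description and members matched only by wording left out, 13 of 14 changed descriptions of LEA and seed storage proteins were higher in KU50. In that form neither list passed (camera adjusted p = 0.118 and 0.0972), and the seed storage list with all its members went both ways. More green or shoot-like tissue in KU50 callus stays open. The photosynthesis list had a median of -0.37, but its members went both ways, with quartiles of -0.72 and 0.30, its call was lost in 9 of 20 settings, and its median was 0.00340 without a filter on dim probes. A mismatch between probes and 1 variety's sequence could move members either way. The share of maturation descriptions higher in KU50 gave a 2-sided exact binomial p of 0.0680 after multiplying by the number of lists, from 0.00184 before, so mismatch stays open. Longer culture on the medium cannot be told apart from variety, because 0 varieties were sampled at more than 1 time.

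More probes were detected in KU50 alone than in 60444 alone, by a ratio of 1.78. Among probes with a bound of at least 4-fold the counts were 275 and 101 and the ratio was 2.72, which argues against a detection threshold as the whole source. Of all probes on the array, 3.19% of those for FGENESH models and 3.25% of those for JGI transcripts were limited to 1 variety. The share was 2.15% for transcripts named EST_CAS, 1.44% for EST contigs, 1.31% for reads from 454 sequencing and 1.25% for other ESTs, so sequenced transcripts were not all alike. Of tested probes the shares were 11.6% for FGENESH models, 5.15% for JGI, 4.26% for EST_CAS and 1.56% to 1.92% for the others, with 27.5% of the FGENESH probes tested. Sequence differences between the varieties could also give such probes, and stay open, because 0 genome sequences of the varieties were set against the probes.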
